A study of Daucus carota subsp. sativus with 2 samples.

How the data were processed

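Poly(A)-selected RNA from carrot roots was sequenced, 1 library from a red variety and 1 from an orange hybrid, per the labels. The group of each library was taken from its title. Of the steps between the reads and the tables, the submitters' processing notes name FastQC, cutadapt, HISAT, HTSeq and DESeq, with no versions or roles. The genome build, the annotation and the settings of these tools are not given in the sources used here.

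The authors deposited a table of read counts per transcript for both libraries, with a protein name and a gene name for most rows. They also deposited normalised counts, a signal that was found here to be the read count multiplied by 1 constant per library, 0.937 for red and 1.07 for orange. The authors' comparison tables hold a fold, the ratio of normalised counts in orange over red. The log2 of that fold is in the same deposited tables, and the largest gap between it and the log2 of the quotient of their own columns was 4.97e-14. A p-value and an adjusted p-value per transcript are given in the authors' deposited tables; how the dispersion was set with 1 library per group is not given in the sources used here. The header text of these tables names the comparison in the opposite order to the quotient they hold, so the direction used here was taken from the columns of values.

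The count table has 19838 transcripts. The protein name of 16161 of them (81.5%) was uncharacterized or missing, which leaves 3677 with an informative name, and gene lists can only find members among the latter. The 160 rows with no protein name hold 1.27% of the counts in red and 0.827% in orange; they have transcript identifiers and were kept. None (0) of the 15464 distinct carrot locus tags in the table matched the reference gene table, so no coordinates are given, and genes carry the names in the deposited table. A list of organelle-encoded genes by contig had been planned and had 0 members, since the table gives no contigs.

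Counts were divided by median-of-ratios size factors, 1.07 for red and 0.937 for orange. A transcript was measured if its mean scaled count was at least 10, which kept 14868. The log2 fold is orange over red with a pseudocount of 0.5 on scaled counts; ratios in the text are of scaled counts without a pseudocount. Each ratio has a 95% exact Clopper-Pearson interval made from the pair of counts. Intervals and floors cover counting error only. A ratio against a count of 0 is given as a bound against a floor of 3 counts in that library. With 1 library per group there is no estimate of the spread between plants. No p-value or standard error for a difference between the varieties was therefore made here, and any statement on a difference is about these 2 libraries.

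Gene lists, written as patterns on protein names, and the rule for naming genes were fixed before the data were examined. There were 41 lists, of which 29 had at least 5 measured members. The median log2 fold of a list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and the list was said to stand apart below percentile 2.5 or above 97.5. The tail share is 2 times the smaller of the shares of random lists below and above the list median, with ties split evenly. It was adjusted over the 29 lists by the Benjamini-Hochberg procedure. The smallest value that 10000 lists can give before adjustment is 2.0e-04. Random lists treat their members as independent, which near-identical copies in a list are not. These are descriptions of 2 libraries. A list of Calvin cycle and photorespiration enzymes was added after the data were seen.

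The rule for naming genes takes the measured members of the carotenoid biosynthesis and carotenoid cleavage lists, the 10 transcripts with the largest log2 fold in each direction among 1917 with an informative name and a mean scaled count of at least 100, and, for each other list that stood apart, the 2 members of highest mean count among those at least 2-fold different in the list's direction. It names 60 transcripts, and others are said to have been chosen after their values were seen. Families within a list, such as laccases or ethylene receptors, were also singled out after their values were seen. Members of gene families with near-identical copies, such as chlorophyll a-b binding proteins, can exchange reads in counting, so single copies are less certain than the sum over a family.

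The procedure was tested on simulated Poisson counts for the orange against red comparison, with the real mean counts and library sizes and 200 transcripts given known folds. Of the 14881 transcripts measured there, the 2-fold rule called 51.4% of the 70 transcripts changed by 2-fold, which sit at the threshold, and 100% of the 72 changed by 4-fold and of the 57 changed by 8-fold. It called 0.415% of unchanged transcripts, and the intervals held the true fold for 95.6%. The simulated counts hold counting error alone, which is what the intervals assume, and no spread between plants. These values therefore check the procedure and give no rate of false calls for the 2 real libraries. The list test used the real folds, not the simulated counts, with fewer random lists for comparison than the main run. Of 200 random lists of 15 transcripts, 6.5% stood apart, and 93.0% of them did when shifted by 2 on the log2 scale. These transcripts were drawn independently, so the 6.5% does not cover lists of related copies.

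Alternatives were TMM and upper-quartile factors from edgeR, total-count scaling, the authors' normalised counts, a pseudocount of 5, no filter and a minimum mean of 50, leaving out the 10 most abundant transcripts, thinning red to the depth of orange, folds without the counting interval, minimum counts of 5 and 50 for transcripts seen in one library, unmatched random lists and list means. Added after the data were seen were scaling on cytosolic ribosomal proteins, random lists from informatively named transcripts, zero counts at their bound, and counts without the photosynthetic, chlorophyll, Calvin cycle and photorespiration lists. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for scaling factors alone.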

Results

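Root transcriptomes of a red and an orange carrot available in India were compared, with 1 library per variety, so no difference has a replicate check. The red library held 11310179 counts and the orange library 7432754. Reads were found for 18216 transcripts in red and 17605 in orange, and 15983 had reads in both.

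The libraries differed at more than 50% of the measured transcripts. Of 14868 transcripts, 4524 (30.4%) were at least 2-fold higher in the red library with a counting interval that excluded equality, and 3622 (24.4%) were at least 2-fold higher in the orange library. At 4-fold the counts were 2917 for red and 1849 for orange, and 6676 transcripts (44.9%) differed by less than 2-fold. Which library had more of the higher transcripts depended on scaling. Orange had 44.5% of the 2-fold differences in the main scaling and 57.8% (5025 against 3669) when libraries were scaled to their total counts, which moves the log2 folds by a median of 0.42 toward orange.

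**Figure D1:**
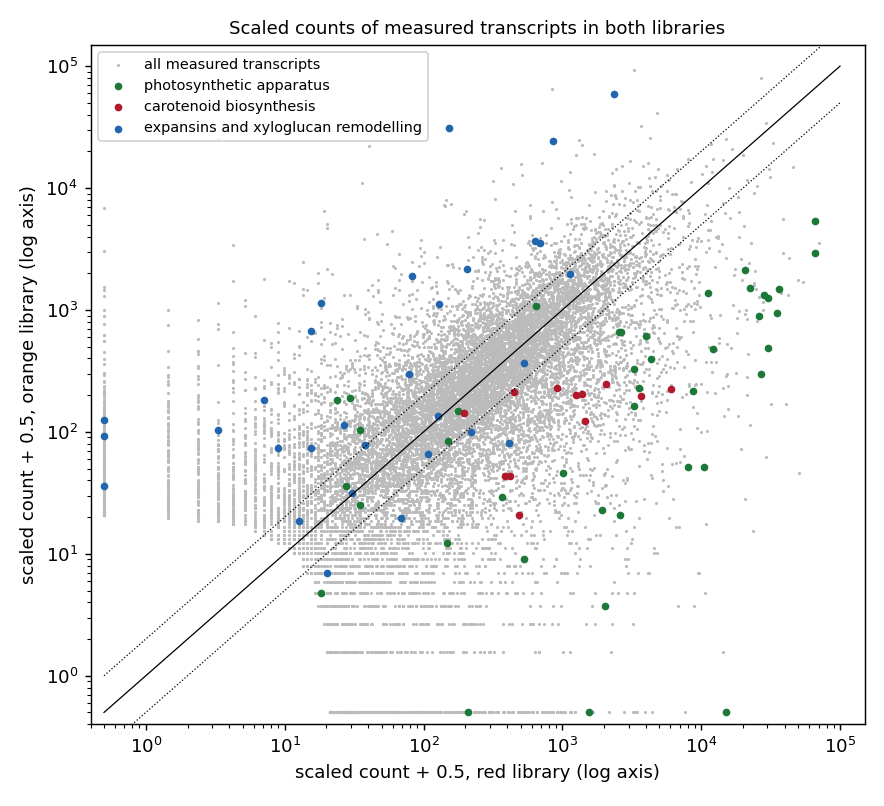
Scaled count plus 0.5 of each measured transcript in the red library (x axis) and the orange library (y axis), both on log axes; the solid line marks equal values and the dotted lines 2-fold differences. Of the 42 photosynthetic apparatus transcripts 34 were at least 2-fold higher in red, as were 11 of the 12 carotenoid biosynthesis transcripts, and 20 of the 30 expansin and xyloglucan transcripts were at least 2-fold higher in orange.

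Carotenoids give carrot roots their colour, and the measured transcripts named for their synthesis were higher in the red library. Of 12 measured carotenoid biosynthesis transcripts, 11 were at least 2-fold higher in red and none (0) in orange. The largest ratios were for zeaxanthin epoxidase (ZEP, 6464 counts in red and 210 in orange, 27.0-fold, interval 23.6 to 31.2), phytoene synthase (PSY1, 522 and 19, 24.1-fold, 15.3 to 40.4), which makes the first carotenoid of the pathway, and lycopene epsilon-cyclase (LCYE, 3945 and 185, 18.7-fold, 16.2 to 21.8). The desaturation and isomerisation steps that lead to lycopene were also higher in red. Phytoene desaturase was 8.40-fold and 8.98-fold higher for its 2 PDS transcripts, zeta-carotene desaturase 11.8-fold (ZDS-1) and 6.81-fold (ZDS2), and carotenoid isomerase (CRTISO) 6.33-fold. Beta-carotene hydroxylase (BCH-2) was 9.77-fold higher and CYP97B3 3.98-fold. The ratio was smaller for lycopene beta-cyclase (LCYB1, 475 and 198 counts, 2.11-fold, 1.78 to 2.4997), the enzyme that turns lycopene into beta-carotene, and neoxanthin synthase (NSY-1) was 1.38-fold higher in red (1.10 to 1.72). The median log2 fold of the list was -3.11, at percentile 0.01 of the random lists (adjusted tail share 0.00116). With total-count scaling LCYB1 was under 2-fold (log2 -0.66) and NSY-1 near equality (log2 -0.04). Transcripts of the photosynthetic apparatus were higher in the same library by a median of 17.8-fold, so the carotenoid difference should not be read as one of root colour alone.

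**Figure D2:**
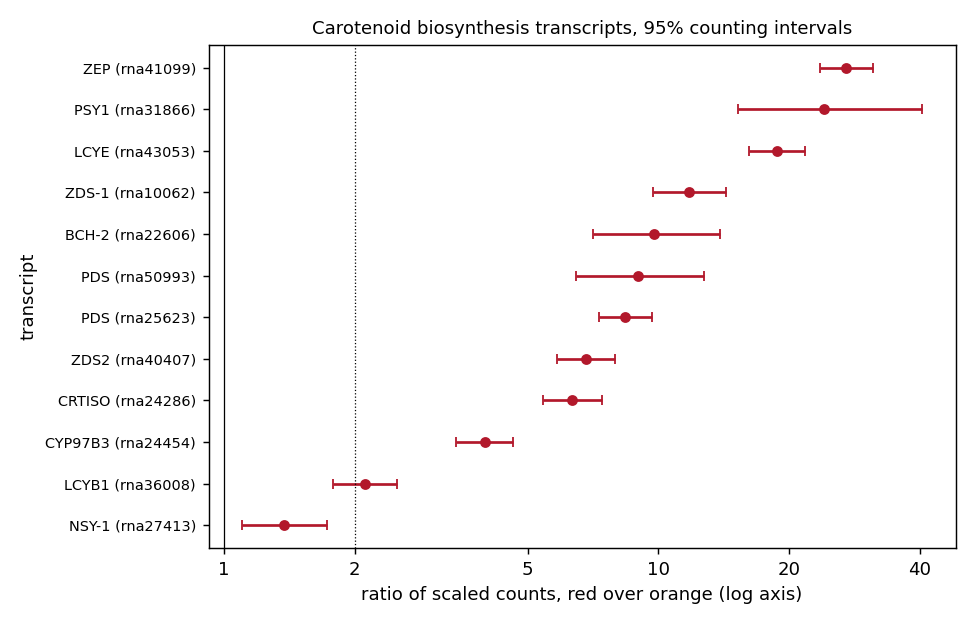
Ratio of scaled counts, red over orange, on a log axis for the 12 measured carotenoid biosynthesis transcripts, with 95% intervals that cover counting error only; the solid line marks a ratio of 1 and the dotted line 2. The ratios run from 1.38 for NSY-1 to 27.0 for ZEP.

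Upstream, 9 of 11 transcripts of the MEP pathway and prenyl diphosphate synthesis, which supply the carotenoid precursors, were at least 2-fold higher in red and none (0) in orange. 1-deoxy-D-xylulose-5-phosphate reductoisomerase (DXR-1) was 8.72-fold higher (7.53 to 10.2) and the synthase DXS-1 5.22-fold (4.62 to 5.92). The most abundant member, the synthase DXS-3 (6190 and 3669 counts), was 1.48-fold higher in red (1.42 to 1.54). It was chosen after its values were seen. The summed scaled counts of the list were 2.55-fold higher in red. The list median was -1.80 at percentile 1.68, with an adjusted tail share of 0.0750, and the list no longer stood apart when its mean was used (percentile 4.22). Photosynthetic transcripts (median -4.15) and those of the Calvin cycle and photorespiration (median -3.81) were higher in the same library. Carotenoid cleavage enzymes went both ways. The 2 CCD1 transcripts were 123-fold (1676 and 12 counts, 70.0 to 238) and 3.79-fold higher in red, NCED4-CCD4 was 37.4-fold higher (22.5 to 67.1) and NCED-2 3.30-fold. NCED-9, a 9-cis-epoxycarotenoid dioxygenase of the kind that starts abscisic acid synthesis, had 0 counts in red and 520 in orange and was at least 197-fold higher in orange. The 5 cleavage transcripts did not stand apart as a list (median -1.92, percentile 5.52), nor did the 8 of abscisic acid synthesis and response (median -1.15, percentile 6.10), which share 3 of the same members; the other 5 are hydroxylases that break abscisic acid down.

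Genes of photosynthesis were far higher in the library labelled red root. Of 42 measured transcripts of the photosynthetic apparatus, 34 were at least 2-fold higher in red and 3 in orange, and together they took 4.61% of all counts in red (4.60 to 4.62) and 0.325% in orange (0.321 to 0.329). The light-harvesting protein CAB37 had 70333 counts in red and 5000 in orange (12.4-fold, 12.005 to 12.7), a second chlorophyll a-b binding protein (DCAR_028844) 70213 and 2730 (22.6-fold, 21.7 to 23.5), and LHCA6, of the same family, 1648 and 0 (at least 482-fold). The RuBisCO small chain RBCS had 16192 counts in red and 0 in orange, at least 4740-fold higher in red, while another small chain transcript, chosen after its values were seen, had 25 and 172. The list median was -4.15, at percentile 0 (adjusted tail share 0.00116). In chlorophyll biosynthesis, 4 of 5 transcripts were at least 2-fold higher in red, with a median of -2.21 that did not stand apart (percentile 12.7). The added list of Calvin cycle and photorespiration enzymes had 17 of 30 transcripts higher in red and 3 in orange, with a median of -3.81 at percentile 0 and 3.33% of counts in red against 0.427% in orange.

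Among other pigment and aroma pathways, all 5 measured flavonoid transcripts were at least 2-fold higher in red. Chalcone synthase CHS2, the entry enzyme of the pathway, had 2444 counts in red and 2 in orange, a ratio of 1073 (297 to 8867), and flavonol synthase FLS-2 had 1325 and 0 (at least 388-fold). The flavonoid median was -5.77 at percentile 0.02 (adjusted tail share 0.00193), and was -2.25 without the filter on low counts. Terpene synthases, which make aroma compounds, were higher in red for 12 of 19 transcripts and higher in orange for 3, with a median of -3.17 at percentile 0 (adjusted tail share 0.00116). Sesquiterpene synthase 2 (STS2) was 39.9-fold higher in red (35.0 to 45.6) and S-linalool synthase (LINS) 8.47-fold (7.38 to 9.77), whereas terpene synthase like-2 had 3 counts in red and 725 in orange, a ratio of 275 in favour of orange (93.8 to 1337). That list also took in 2 squalene enzymes, which belong to sterol synthesis; 1 of them was among the 3 higher in orange. Both pathways were higher in the library with 4.61% of its counts in photosynthetic transcripts.

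The general phenylpropanoid and lignin list had members higher in each library. Its median was 1.29 toward orange, at percentile 99.75 (adjusted tail share 0.0207), with 10 of 18 transcripts higher in orange and 3 in red, but its summed scaled counts were 1.81-fold higher in red. Laccases, which polymerise lignin, made up 10 of the members and 8 of them were higher in orange, such as DCAR_015633 (125 and 274 counts, 2.496-fold, 2.01 to 3.11). Cinnamyl alcohol dehydrogenase was 2.83-fold higher in orange (2.60 to 3.09). Phenylalanine ammonia-lyase, the entry enzyme, had 3 transcripts, of which 2 were at least 2-fold higher in red. These enzyme groups were singled out after their values were seen, and the difference between them was not tested. The list no longer stood apart without the filter on low counts (median 0.29) or with a minimum mean of 50 (median 0.43). Cytochrome P450s had 8 of 17 transcripts higher in red and 1 in orange, with a median of -1.17 at percentile 2.385, which passed the limit narrowly (adjusted tail share 0.0988) and was lost under 8 alternatives (median -0.54 without the filter on low counts). The list includes 3 P450 reductases, none of them (0) at least 2-fold different. CYP97A, a carotenoid hydroxylase, was 43.4-fold higher in red (33.1 to 58.1) and CYP72A397 2.89-fold. Glycosyltransferases, matched by name and including 7 dolichol-linked enzymes of protein glycosylation that are not UDP-glycosyltransferases, did not stand apart (86 transcripts, median -0.32, percentile 10.9), but they stood apart toward red, at percentile 0, without the filter on low counts (median -1.19) and when their mean was used (-1.44). With total-count scaling their median was 0.09.

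Most transcripts of starch metabolism, phloem protein 2-2 and lipoxygenases were higher in red. In starch metabolism 9 of 15 transcripts were at least 2-fold higher in red and 4 in orange (median -1.61, percentile 1.53, adjusted tail share 0.0740). ADP-glucose pyrophosphorylase DCAR_030612, which makes the substrate of starch synthase, had 3587 counts in red and 0 in orange (at least 1050-fold), a starch synthase (DCAR_008624) was 61.2-fold higher (47.9 to 79.6) and a glucan phosphorylase (DCAR_030028) 141-fold (95.8 to 215). Sucrose metabolism and sugar transport went both ways, with 7 of 13 transcripts higher in red and 4 in orange (median -1.19, percentile 6.63). With a minimum mean of 50 this list stood apart toward red (median -2.22, percentile 2.03), and with total-count scaling its median was -0.04. Of 6 phloem transcripts 5 were at least 2-fold higher in red and 1 in orange (median -3.12, percentile 1.32, adjusted tail share 0.0740). The 5 are all copies of phloem protein 2-2, led by a PP2-2 transcript with 23606 counts in red and 2279 in orange (9.10-fold, 8.71 to 9.501) and another at 5.93-fold (5.56 to 6.33). The member outside that family, a sieve element occlusion protein singled out after its values were seen, had 37 and 109 counts and was 3.35-fold higher in orange (2.29 to 5.01). In the jasmonate list 6 of 9 transcripts were higher in red and 1 in orange (median -2.73, percentile 0.775, adjusted tail share 0.0562), and 8 of its members are lipoxygenases, which also act outside jasmonate synthesis. Allene oxide synthase AOS2 was 55.2-fold higher in red (47.0 to 65.3) and lipoxygenase DCAR_026417 2.19-fold (2.13 to 2.25; log2 -0.71, under 2-fold, with total-count scaling). The photosynthetic list was higher in the same library as each of these groups.

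The orange library was higher in genes of cell wall loosening and auxin response. Variety and library coincide, so a difference between varieties cannot be told here from one in the tissue taken. Of 30 expansin and xyloglucan remodelling transcripts, 20 were at least 2-fold higher in orange and 4 in red, and they took 1.68% of counts in orange against 0.0754% in red. A xyloglucan endotransglucosylase/hydrolase (DCAR_025835), an enzyme that cuts and rejoins wall xyloglucan, had 2499 counts in red and 55616 in orange (25.3-fold, 24.3 to 26.4), and DCAR_029685 had 163 and 29201 (204-fold, 175 to 239). The list median was 2.45 at percentile 100 (adjusted tail share 0.00116). Of 63 auxin synthesis and response transcripts, 35 were higher in orange and 12 in red (median 1.34, percentile 100, adjusted tail share 0.00116). Despite the list's name, its members were auxin response factors, auxin-responsive or auxin-induced proteins and auxin efflux carriers, which transport auxin, rather than synthesis enzymes. The auxin-responsive proteins DCAR_012517 and POPTR_010G078400v3 were each 9.03-fold higher in orange. Cellulose synthesis and xylem markers had 8 of 13 transcripts higher in orange and none (0) in red (median 1.05, percentile 98.6, adjusted tail share 0.0740). Cellulose synthases DCAR_006225 and DCAR_022397 were at 2.24-fold (2.09 to 2.39) and 2.08-fold (1.86 to 2.33). The most abundant ones, chosen after their values were seen, were under 2-fold: DCAR_029673 (log2 0.12), DCAR_001143 (-0.33) and DCAR_001518 (0.70). Summed scaled counts of the list were 1.17-fold higher in orange. Dividing-cell genes, mostly histones, had 13 of 31 transcripts higher in orange and 7 in red (median 0.82, percentile 99.1, adjusted tail share 0.0603). Histone H2A transcripts of DCAR_002780 (139 and 3063 counts) and DCAR_010013 were 25.1-fold (21.2 to 30.0) and 15.2-fold (12.1 to 19.2) higher in orange. A second DCAR_002780 transcript (173 and 92 counts), chosen after its values were seen, was 1.65-fold higher in red (1.28 to 2.15). Of 26 histone transcripts 12 were at least 2-fold higher in orange and 7 in red. The only other member at least 2-fold higher in orange was a cyclin-dependent kinase inhibitor (DCAR_024480, 8 and 29 counts). Proliferating cell nuclear antigen (32 and 50 counts) was 1.78-fold higher in orange, and the cyclin-dependent kinase regulatory subunits differed under 2-fold. These members were also chosen after their values were seen. Neither the cellulose list (percentile 97.2) nor the dividing-cell list (percentile 97.3) stood apart with a minimum mean of 50, and the dividing-cell mean was 0.16, at percentile 78.0.

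**Figure D3:**
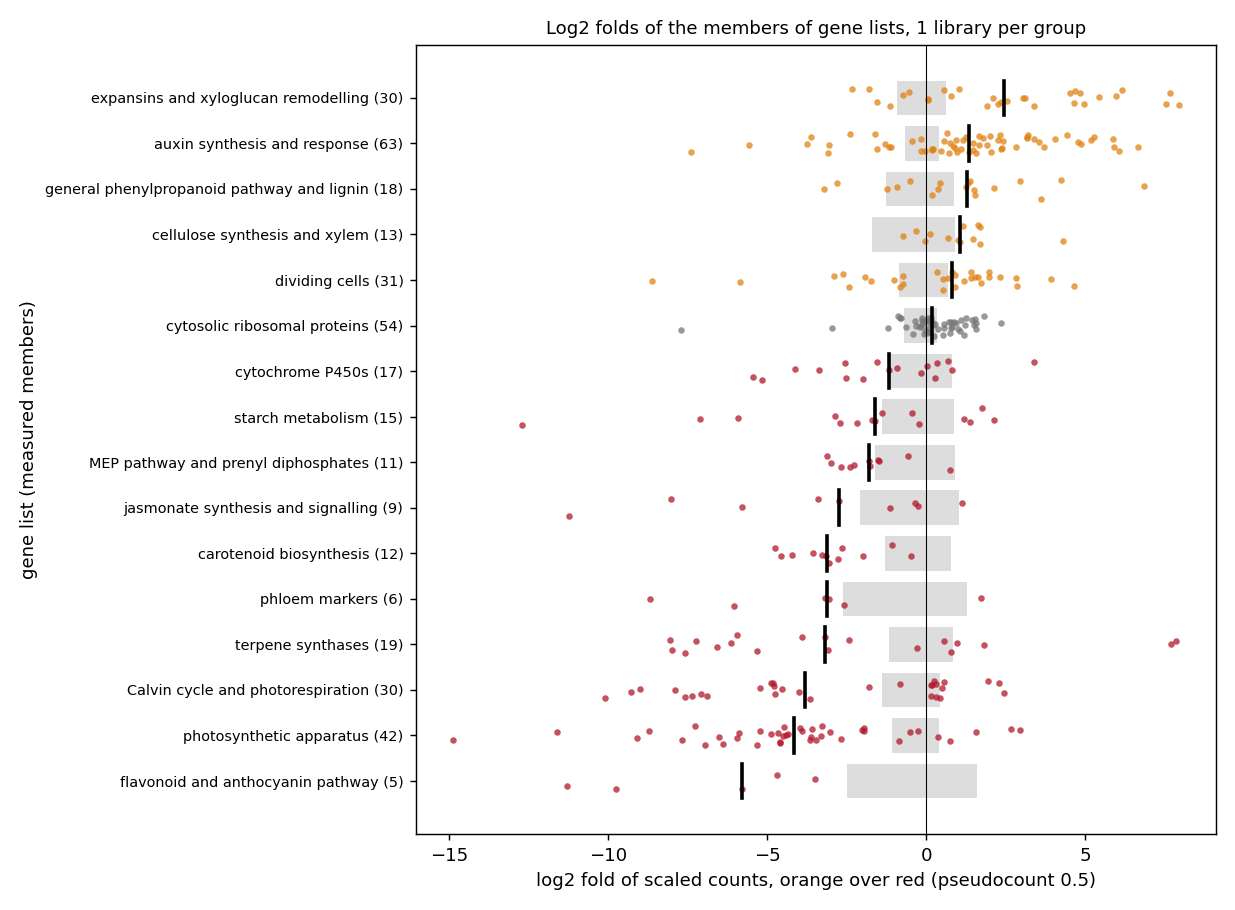
Log2 fold, orange over red, of each measured member (points) of the lists that stood apart, of the Calvin cycle and photorespiration list added after the data were seen, and of cytosolic ribosomal proteins for reference (grey points); black bars are medians and grey boxes hold the middle 95% of random list medians. The medians run from -5.77 for flavonoids to 2.45 for expansins and xyloglucan remodelling, and ribosomal proteins sit at 0.20.

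Of the 29 lists with at least 5 measured members, 9 stood apart toward red, 5 toward orange and 15 did not, and 7 had an adjusted tail share under 0.05. Cytosolic ribosomal proteins, used as a reference, had a median of 0.20 (54 transcripts, percentile 91.3), and stood apart toward orange when the mean was used (0.21, percentile 98.4). Pectin remodelling (48 transcripts) was at 0.40 and percentile 95.6, and ethylene synthesis and response (7 transcripts) at 1.01 and percentile 95.3. All 3 ethylene receptors in that list were at least 2-fold higher in orange, while 2 of its 7 members are methylenetetrahydrofolate reductases matched by name alone. Heat shock proteins (0.32, percentile 77.5), defence proteins (0.07, percentile 57.4), resistance genes of the NBS-LRR class (-0.76, percentile 12.5), cytokinin genes (0.58, percentile 83.5), antioxidant enzymes (-0.55, percentile 6.16), periderm and suberin markers (-0.06, percentile 50.2) and transposable element proteins (0.10, percentile 72.8) did not stand apart. The median and the mean had the same sign in all 29 lists. The other 12 lists had under 5 measured members, 5 of them none: plastid carotenoid storage, MYB and NAC factors, dehydration and cold, and organelle-encoded genes. Among the rest, the aquaporin PIP2-2 was at 4.84, the gibberellin-linked Snakin-2 at 5.90, a FAD2-like desaturase at 2.08 and a phytochrome at 0.64. The medians of the 3 fermentation, 4 WRKY and 4 flowering transcripts were -0.08, -0.67 and 0.93.

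The 10 largest log2 folds in each direction were taken from the 1917 transcripts with an informative name and a mean scaled count of at least 100, and transcripts outside these limits are not ranked here. All but 1 of these transcripts had fewer than 10 counts in the other library, the exception being xyloglucan endotransglucosylase/hydrolase DCAR_029685 (163 in red). Toward red, RBCS ranked first among these by log2 fold, but with 0 counts in orange its place rests on the pseudocount. A hexosyltransferase had 8169 counts against 0 (at least 2392-fold). ATP-dependent DNA helicase (1312 against 0), rRNA N-glycosidase (1231 against 0) and a DETOXIFICATION transporter (1036 against 0) were at least 384-fold, 360-fold and 303-fold higher. Lipoxygenase DCAR_001406 had 9431 counts against 3, a ratio of 2761 (944 to 13391), and a DC2.15-like protein 11321 against 4, a ratio of 2486 (971 to 9125). The bound for RBCS, at least 4740-fold, lies inside both intervals, so which transcript differed most toward red is not settled. Toward orange, NCED-9 ranked first among these by log2 fold, but with 0 counts in red its place rests on the pseudocount. An endoglucanase (DCAR_018320) had 702 counts against 1, a ratio of 799 (143 to 31615). A pectate lyase (DCAR_016430), which cuts pectin, had 769 against 2, a ratio of 438 (121 to 3622). The bound for NCED-9, at least 197-fold, lies below both ratios, so which of them differed most is not settled. UDP-glycosyltransferase 5 was 273-fold higher (132 to 680) and isocitrate lyase 229-fold (97.6 to 706). An acyl-carrier-protein desaturase (204 against 0), a trehalose 6-phosphate phosphatase (195 against 0) and a PRONE domain protein (193 against 0) were at least 77.4-fold, 74.0-fold and 73.3-fold higher in orange.

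With at least 10 counts in one library and 0 in the other, 721 transcripts had reads in red only and 419 in orange only. At a minimum of 100 counts these numbers were 155 and 63, and the largest counts were 16192 in red and 6430 in orange. A count of 0 allows up to 2.81 scaled counts in red and 3.20 in orange. The 10 most abundant transcripts held 4.98% of counts in red (4.97 to 4.99) and 6.14% in orange (6.12 to 6.15), and the top 100 held 22.6% and 20.01%.

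The authors' deposited table lists 4064 transcripts as up, 4567 as down and 7352 as neutral, with 2233 in red only and 1622 in orange only. Its folds were orange over red, from the same counts and scaling constants as used here, so the 2 sets of folds differ only through the pseudocount and one is no check of the other. Among transcripts with reads in both libraries, 875 had a p of at most 0.05 in the authors' deposited table, 273 up and 602 down, and 6 had an adjusted p of at most 0.05, 1 up and 5 down. In the one-library sheets of the authors' deposited table, another 44 red-only and 13 orange-only transcripts had an adjusted p of at most 0.05. Of the 12 carotenoid biosynthesis transcripts, 1 (PSY1) had a p of at most 0.05 in the authors' deposited table, and the adjusted p ran from 0.541 to 1.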

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

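Chosen after the data were seen were ribosomal protein scaling, random lists from named transcripts, zero counts at their bound, and counts without the green-tissue lists. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. The 5 scalings move a list and its random lists nearly alike, and zero counts at their bound moved 0 list medians, so whether a list stands apart was tested by the other 7 settings. Of the 14 lists that stood apart, 8 did so under all 7: carotenoid biosynthesis, photosynthetic apparatus, terpene synthases, starch, phloem, jasmonate, expansins and auxin. Flavonoids did so under the 6 that could be run, since a minimum mean of 50 leaves under 5 members. No list that stood apart changed sign, nor did any (0) of 477 comparisons of named genes. Only a change of scaling can change the sign of a gene's fold, and none moved log2 folds by a median above 0.42. All named genes but NSY-1 differed at least 2-fold in the main scaling. The gene comparisons could therefore hardly change sign and are no check of direction. Of the 477 comparisons, 73 moved the log2 fold outside the main counting interval, under total-count scaling, upper-quartile scaling or a pseudocount of 5. At a pseudocount of 5, NCED-9 went from 10.12 to 6.81 and RBCS from -14.89 to -11.57. Of the lists that did not stand apart, 3 changed sign without a change of scaling (periderm, defence and cytokinin), and 3 only through the shift a scaling gives all transcripts (glycosyltransferases, transposable elements, and ribosomal proteins under the scaling that centres them). Where a cause is not given, it was not tested. Total-count, upper-quartile and ribosomal protein scaling moved log2 folds by a median of 0.42, 0.25 and -0.20; the authors' normalised counts use the main scaling, and scaling cannot move shares of counts, so these settings test nothing.

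Under total-count scaling the medians of transposable element proteins (0.56), ribosomal proteins (0.62), pectin (0.83) and ethylene (1.43) moved with the overall shift, as did ribosomal proteins (0.45), pectin (0.65) and ethylene (1.26) under upper-quartile scaling, and glycosyltransferases (-0.53) and antioxidant enzymes (-0.74) under ribosomal protein scaling; none of these stood apart. The P450 list no longer stood apart under ribosomal protein scaling (-1.35), pseudocount 5 (-0.91), no filter (-0.54), a minimum mean of 50 (-1.22), its mean (-1.37), and, at -1.17, with unmatched lists, lists from named transcripts or without the 10 most abundant transcripts. Without a filter the phenylpropanoid list (0.29) no longer stood apart, glycosyltransferases (-1.19) did, and ethylene was at 1.24. With a minimum mean of 50 the phenylpropanoid (0.43), cellulose (0.88) and dividing-cell (0.70) lists no longer stood apart and sucrose (-2.22) did. With means, the MEP (-1.80) and dividing-cell (0.16) lists no longer stood apart, glycosyltransferases (-1.44) and ribosomal proteins (0.21) did, and antioxidant enzymes were at -0.98.

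With a minimum mean of 50, fewer transcripts were tested: 1125 were 4-fold higher in orange against 1849, 143 were in red only and 65 in orange only, and the top 10 and top 100 shares were 5.03% and 22.9% in red and 6.22% and 20.3% in orange. Leaving out the 10 most abundant transcripts gave 4.21% and 20.9% in red and 3.65% and 16.8% in orange. One-library transcripts depend on the minimum: at 5 counts 686 in orange only, at 50 counts 274 in red only and 117 in orange only. Counts of 2-fold differences stayed within 1.5 times the main count throughout (3580 and 4328 after thinning red). Dropping green-tissue lists (3616 and 4469) kept 14791 of 14868 transcripts, so tests little.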

Other observations

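The tests of explanations given here were chosen after the results were seen, except the test of same-named copies. Some enzyme families had members that differed in opposite directions; these transcripts were also chosen after their values were seen. Catalase, which removes hydrogen peroxide, had a transcript (Ccrd_016515) with 29894 counts in red and 1085 in orange (24.2-fold higher in red, interval 22.8 to 25.7) and another (DCAR_013924) with 28604 and 74445 (2.96-fold higher in orange, 2.92 to 3.004). A further one (DCAR_022934) had 268 and 0, and the summed scaled counts of 5 catalase transcripts were 1.46-fold higher in orange. Ferredoxin DCAR_012197 was 21.7-fold higher in orange (19.2 to 24.6) and ferredoxin AQUCO_01400068v1 106-fold higher in red (71.9 to 165), while the summed scaled counts of 8 ferredoxin transcripts differed 1.14-fold. Ferredoxin-NADP reductase also went both ways, with DCAR_016600 33.7-fold higher in red (30.7 to 37.1) and DCAR_003854 2.16-fold higher in orange (1.95 to 2.40). The summed scaled counts of these 2 transcripts were 10.3-fold higher in red. In the orange library a mitochondrial formate dehydrogenase (DCAR_021682) was among the most abundant transcripts, with 61369 counts against 901 in red (77.6-fold, 72.6 to 82.9).

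Photosystem proteins that plants usually encode in the plastid did not follow the nuclear ones. Of 5 such transcripts (D1, 2 of CP43, Ycf3 and photosystem I A1) none (0) differed 2-fold beyond the counting interval, with a median of -0.27, whereas 28 of 30 chlorophyll a-b binding protein transcripts were higher in red. RNA was poly(A)-selected, per the labels, which keeps few plastid messages, so these 5 values bear little on the plastids of either root.

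The first pattern is the higher photosynthetic transcripts in the red library. Library scaling was argued against, since the median nearest 0 under any scaling was -3.73. Reads exchanged among the listed transcripts were argued against too, since the summed scaled counts of all members were 18.9-fold higher in red. Reads lost to copies outside the list were not tested. Green-tissue RNA in the red sample is a candidate explanation: the Calvin cycle and photorespiration list, which shares 0 measured members with the photosynthetic list, had a median of -3.81, and carbonic anhydrase (54242 against 43 counts) and glycine cleavage P protein (52935 against 1648) were among its most abundant transcripts. The orange library also had reads for 39 of the 42 photosynthetic transcripts, whose source in that root was not tested. Greening of the red root, green tissue taken with it and a difference between the varieties stay open, and were not tested, since variety and library coincide.

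The second pattern is the higher carotenoid pathway in the red library. Scaling was argued against (the median nearest 0 was -2.69). Reads exchanged among the listed transcripts were argued against too, since their summed scaled counts were 9.94-fold higher in red. The sum runs over different enzymes, so it cannot show reads lost to copies outside the list. Green-tissue RNA may also account for it, because leaves make carotenoids and the carotenoid median lay 1.04 above the photosynthetic median, between it and 0, by more than the counting error (0.82 to 1.39). That test is weak, as a difference between red and orange varieties could give the same value. The carotenoid difference should therefore not be read as one of root colour alone until samples of each root without green tissue are compared.

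The third pattern is the 218 transcripts with at least 100 counts in one library and 0 in the other. Of the 37 that have a same-named copy, 10.8% (3.03 to 25.4) had such a copy at least 2-fold higher in the other library. That lay under the limit of 50% set beforehand for reads moved between copies. Among other measured transcripts at least 2-fold different with a same-named copy, the share was 21.1% (242 of 1149). The limit was a chosen one, and a copy can take reads without becoming 2-fold higher. The test therefore cannot decide how many of the 37 lost reads to a copy. For the other 181 transcripts, copies under another name were not tested. Sequence differences between a variety and the reference, genes missing from one variety and regulation stay open and were not tested.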
